A study of Chlorocebus sabaeus with 3 samples.

How the data were processed

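Cell-free RNA of amniotic fluid supernatant, the fluid that remains once cells have been spun down, was sequenced from 3 vervet monkey (Chlorocebus sabaeus) pregnancies. Per the labels' protocols, RNA was isolated with a kit for circulating nucleic acids, treated with DNase, cleaned on a column and turned into cDNA by single-primer isothermal amplification (the Ovation SPIA chemistry), then sequenced on a HiSeq2500. The submitters' processing notes name bcl2fastq 2.17, STAR and HTSeq. The versions of STAR and HTSeq, the genome build, the annotation and the strand setting are not given in the sources used here. The status labels put 1 sample in each group: stillborn (sex label M), spontaneous abortion (sex label NA) and alive (sex label F).

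The deposited values are RPKM, reads per kilobase of gene scaled to sequencing depth, with 1 value per gene and library and 33994 genes in each file. The step by which the authors made the RPKM values is not given in the sources used here. Neither gene lengths nor library totals stand beside the values. Within a gene, however, the values of the 3 libraries stood in ratios of whole numbers times a fixed ratio per pair of libraries. The totals that make these numbers whole were solved for and came to 17749954 for the stillborn, 29926352 for the spontaneous abortion and 20220899 for the alive library. With them, 99.5% of the 23276 genes above 0 in any library gave whole reads within the rounding of the printed digits. A factor common to all reads of a gene cannot be seen in this way, so each number of reads is a lower bound, and these numbers add up to 95.0% to 95.9% of the totals. On simulated reads with the pattern of zeros of the files, 3 of 3 totals came back exactly, 92.8% of the 15529 genes with reads in every library had the right numbers, and none of those genes lay above the truth. Whether single reads or read pairs were counted is not given in the sources used here.

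Gene names were taken from the files. Of the 17250 names made of LOC and a number, 6491 matched a gene ID in the NCBI RefSeq table of the assembly mChlSab1.0.hap1, and 825 of these took a symbol from it. That table has no genes on a Y chromosome, and since the build behind the files is not given, no coordinates are printed. Of the 16744 other names, 15334 were found in the table. Reads shared between close paralogs, overlapping genes or antisense partners cannot be told apart in these values.

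Libraries were scaled with TMM factors (trimmed mean of M-values) computed from the recovered reads: 0.937 for stillborn, 1.02 for spontaneous abortion and 1.05 for alive. Pairs of libraries were compared without a test, because each status has 1 sample. A gene was counted as apart when its scaled ratio was at least 4-fold, its exact Clopper-Pearson 95% interval, conditional on the sum of both read numbers, excluded 1, and it had at least 30 reads in the higher library. Where a library held 0 reads, the ratio was taken against 3 reads in that library and is not a 95% bound. The bound of the exact interval lies closer to 1. For CCL3 in stillborn against alive it was 12.8-fold, beside a ratio of 16.5. SPIA libraries carry no molecular identifiers, so the intervals cover counting error only. On simulated reads for stillborn against alive over 23150 genes, 99.5% of 200 genes changed 8-fold were recovered and 0 unchanged genes were counted. Those reads held counting error alone, and the changed genes were above the limit of 30 reads. The check gives no rate of false counts between animals or near that limit.

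Gene lists for tissues, cell types and processes were fixed before the data were examined. A list's shift is the median log2 ratio, on the scale log2(RPKM + 0.1) after TMM scaling, of its members with a mean RPKM of at least 1. This scale understates the ratios of low genes. The shift is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Lists with fewer than 5 such members are given by their members' values. Such a percentile describes these libraries and not the conditions. The list of mitochondrially encoded genes and that of X inactivation transcripts had 0 members in the files.

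The pregnancy losses (2 libraries) were set against the alive library (1) with limma 3.58.1 in R 4.3.3, on TMM-scaled log2(RPKM + 0.1) with a mean-variance trend over the 10229 genes with a mean RPKM of at least 1, with Benjamini-Hochberg adjustment at 0.05. That grouping leaves 1 residual degree of freedom, and the lone alive sample is assumed to vary as the losses do. The planned negative binomial count tests were not run because the deposited values are RPKM and not counts, and limma took their place. The model was also run on simulated reads with the same spread between libraries for every gene and no difference between the 2 losses. The shares called there therefore do not give its power on these data. On simulated reads for this comparison over 10210 genes, 100% of the 100 genes changed 16-fold and 100% of the 100 genes changed 64-fold were called, beside 21 unchanged genes, so the share of false calls there was above the nominal level.

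Genes named in the text follow a rule fixed at the same time. It takes, for each pair, the 10 genes with a symbol in each direction whose interval bound nearest 1 lies farthest from it, the 15 genes with a symbol of highest mean RPKM, and up to 4 members of each list by mean RPKM. It adds up to 4 members apart of each list outside the central 95% of random lists, up to 10 genes with a symbol of lowest p from limma in each direction, and every measured Y-linked gene. A few genes named outside this rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here. Alternatives covered the scaling, the filters on reads, the fold, the depth, the pseudocount, the summary of a list and the library set alone. Other software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.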

Results

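The study assessed the fetal transcriptome through the RNA that circulates free of cells in the amniotic fluid of vervet monkeys, an Old World primate. The 3 libraries came from 1 pregnancy that ended in stillbirth, 1 that ended in spontaneous abortion and 1 with a live outcome. They held 17749954, 29926352 and 20220899 assigned reads. At least 10 reads were found for 14766 genes in the stillborn, 15709 in the spontaneous abortion and 14882 in the alive library, and for 13597 genes in all 3. No status has a second sample, so the pairwise comparisons set library against library and not condition against condition, without a p-value. Their intervals cover counting error only.

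The RNA of all 3 fluids was led by the imprinted pair H19 (listed as LOC103241849), a long non-coding RNA of fetal tissue, and IGF2, the fetal growth factor encoded beside it. H19 had a mean RPKM of 35064 ± 4211 (SD, n = 3 libraries) and IGF2 one of 26422 ± 8313. Together they held 16.9% of the summed RPKM in the stillborn, 16.2% in the spontaneous abortion and 12.3% in the alive library. TPT1, a growth-related translationally controlled protein, followed at 6123 ± 1963 and EEF1A1, the translation elongation factor, was at 4388 ± 894. FTL, the ferritin light chain, reached 4015 ± 729, and VIM, the intermediate filament of mesenchymal cells, 2929 ± 608. The calcium-binding S100A6 and S100A11 had means of 2344 ± 627 and 2326 ± 583. The 72 measured ribosomal protein genes summed to RPKM 61198 in the stillborn, 46064 in the spontaneous abortion and 55877 in the alive library. As shares of the summed RPKM these were 14.06%, 12.09% and 14.02%.

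Epithelial and secretory transcripts were abundant. WFDC2, a secreted whey acidic protein of epithelia, stood at RPKM 1736 in the stillborn, 2378 in the spontaneous abortion and 2545 in the alive library, and DEFB1, an epithelial defensin, at 689, 565 and 537. The simple epithelial keratin KRT19 was at 316, 434 and 554, and the basal keratin KRT5 at 49.1, 151 and 151, in the same order. Lumican (LUM), a matrix proteoglycan, was at 222, 239 and 158. Of hepatic and intestinal transcripts, the apolipoprotein APOA2 was at 146, 208 and 189 and the fatty acid binding protein FABP1 at 80.2, 31.8 and 48.6. HTRA4, a placental serine protease, was at 13.5, 13.6 and 13.5, and the muscle troponin TNNT1 at 15.8, 8.25 and 25.9. These single genes stood above most of their lists. In each library 3 of 11 measured trophoblast genes and 3 of 15 muscle genes reached RPKM 1. Median RPKM was 0.0602, 0.133 and 0.107 for the trophoblast list and 0.00111, 0.0280 and 0.0766 for the muscle list. For the liver list it was 0.731, 0.695 and 0.531.

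The kidney, lung, erythroid, endothelial and neuronal lists also left little RNA. Of 15 measured kidney genes, 3, 6 and 6 had at least 10 reads in the stillborn, spontaneous abortion and alive libraries, and none reached RPKM 1 in any of them. Their highest mean was that of CUBN, an endocytic receptor of the proximal tubule, at 0.932, 0.640 and 0.329. Of the lung list, the club cell secretoglobins SCGB1A1 and SCGB3A2 passed RPKM 1 in the stillborn library, at 3.84 and 2.68, against 0.672 and 0.131 in the spontaneous abortion and 0.952 and 0.796 in the alive library, and the surfactant gene SFTPC was at 0.782, 0.0386 and 0.0286. Beta globin (HBB, listed as LOC103247901) was at 0.162, 1.82 and 0.213, and no endothelial gene on the list reached RPKM 1. Of the neuronal list, SYN1, a synaptic vesicle protein, passed RPKM 1, at 6.64, 4.81 and 4.70. Among 19 genes tied to neurodevelopmental disorders, DYRK1A was at 10.4, 12.7 and 12.4, and of 39 homeobox genes, HOXB4 was at 1.23, 2.13 and 3.91.

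The first comparison asks how the fluid of the stillborn pregnancy differed from that of the live one. Squamous and inflammatory transcripts were higher in the stillborn library, and genes of DNA replication and mitosis were lower. PDPN, a membrane mucin of lymphatic endothelium and basal keratinocytes, was 107-fold higher (95% interval 79.4 to 148). The salivary mucin MUC7 was 175-fold higher (67.8 to 643), and the protease inhibitor SPINK6 of the epidermis 106-fold higher (69.4 to 172). SPRR3, a cornified envelope protein of oral and oesophageal epithelium, was 57.7-fold higher (47.4 to 71.0), and FLG2, a filaggrin-like protein of the cornified layer, 107-fold higher (45.6 to 332). In total, 630 genes were apart as higher and 433 as lower in the stillborn library, or 565 and 513 on the scale of total assigned reads.

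The oral and oesophageal squamous list had a median log2 ratio of 1.83, above all 10000 matched random lists at a percentile of 100, with 9 of 9 members above 0. On the scale of total assigned reads 8 of the 9 were above 0. The cornified cell protein CRNN was 33.2-fold higher (27.9 to 39.7), the raft protein MAL 6.34-fold (5.39 to 7.50) and the keratin KRT6A 4.87-fold (4.77 to 4.97). Epidermal genes had a median of 1.49 at a percentile of 100, with 8 of 10 members above 0. Of the 14 measured, 5 were apart as higher and 1 as lower. KRT14 was 9.37-fold higher (8.04 to 11.0), SBSN 6.74-fold (3.98 to 12.1), KRTDAP 6.14-fold (5.09 to 7.44) and the desmosomal DSG1 4.93-fold (4.57 to 5.32). KRT5, the usual partner of KRT14, went the other way, at RPKM 49.1 in the stillborn against 151 in the alive library.

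Inflammatory genes had a median of 1.26 over 6 members, at the 99.98th percentile. The 4 with the highest mean RPKM were SOD2, IL1RN, NFKBIA and TNFAIP3, with IL1RN at RPKM 42.1 against 22.4. ICAM1, an adhesion molecule for leukocytes, was 10.8-fold higher (7.54 to 15.9) and the cytokine IL6 6.80-fold higher (4.72 to 10.1). The chemokine CCL3 was 16.5-fold higher, with 0 reads in the alive library taken as 3. Its mean RPKM was under 1, so it did not enter the median. CCR1, a chemokine receptor of myeloid cells, was 288-fold higher (51.1 to 11411), with 1 read in the alive library. Myeloid markers stood beside this group. S100A8, a calgranulin of neutrophils and monocytes, was at RPKM 7.11 against 0 and S100A9 was 10.4-fold higher (5.93 to 19.6), the gelatinase MMP9 was at 3.43 against 0.337, and the complement gene C1QB at 4.35 against 1.05. Lactotransferrin (LTF), on the neutrophil list as well, was at 33.3 against 105. Of 14 lymphocyte genes, 1 was apart as higher and 2 as lower in the stillborn library, GNLY, the granulysin of cytotoxic cells, at 5.24-fold lower (3.30 to 8.73) and GZMB, a granzyme, at 4.18-fold lower (2.89 to 6.23).

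Cell cycle genes lay on the low side, with a median of -1.55 at a percentile of 0 and all 15 members below 0 under each of 3 scalings. MCM5, a subunit of the replicative helicase, was 6.97-fold lower (4.80 to 10.5), MCM7 4.49-fold lower (3.62 to 5.62) and BUB1, a spindle checkpoint kinase, 4.48-fold lower (3.55 to 5.72). RRM2, the ribonucleotide reductase subunit, was at RPKM 19.1 against 79.9 and TOP2A, the mitotic topoisomerase, at 8.59 against 36.3. Outside the lists, RTL1, an imprinted gene derived from a retrotransposon, was 108-fold lower and BNC1, a transcription factor of basal keratinocytes, 39.0-fold lower. Both had 0 stillborn reads, taken as 3. The hair keratin KRT35 was 45.4-fold lower (20.7 to 125), the bradykinin receptor BDKRB1 43.7-fold (14.7 to 214), the netrin receptor UNC5C 37.5-fold (12.6 to 184) and the imprinted Notch ligand DLK1 20.8-fold (12.3 to 38.5). IGF2 was 2.13-fold higher in the stillborn library (2.13 to 2.14). The liver, intestinal, simple epithelial, fibroblast, heat shock, interferon, antimicrobial, hypoxia, unfolded protein, immediate early, p53, imprinted, neurodevelopmental and ribosomal protein lists all lay within the central 95% of random lists, but with the mean in place of the median the imprinted list lay below it, at -0.55.

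**Figure D1:**
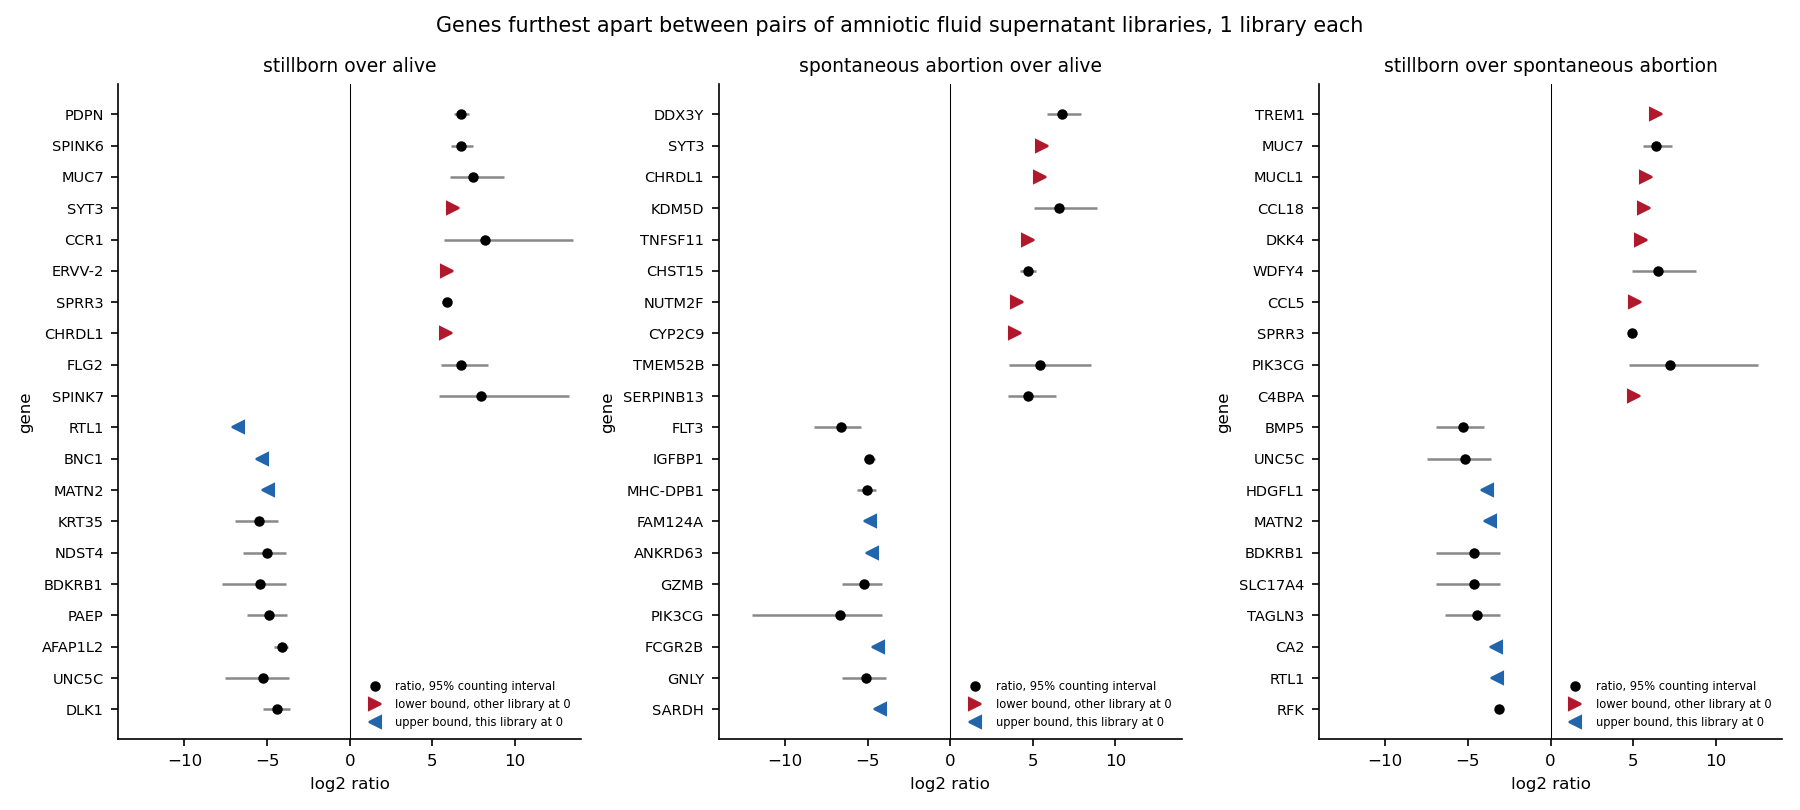
Log2 ratios of the 10 genes with a symbol farthest from 1 in each direction for each pair of libraries. Lines are 95% counting intervals, and triangles are genes for which a library held 0 reads. Each panel compares 1 library with 1. PDPN, SPINK6 and MUC7, whose intervals lie farthest from a ratio of 1 for stillborn over alive, stand at 6.74, 6.73 and 7.45, and CCR1, with a wider interval, at 8.17.

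The next comparison asks the same of the spontaneous abortion. The differences were fewer, with 316 genes apart as higher and 207 as lower, and with 196 and 176 once every library was thinned to the smallest total. Of the genes with a symbol, the Y-linked DDX3Y, an RNA helicase, had the interval farthest from 1, at 108-fold higher (56.9 to 237), and the Y-linked KDM5D, a histone demethylase, was 97.7-fold higher (33.2 to 476). CHST15, a chondroitin sulfate sulfotransferase, was 25.9-fold higher (18.7 to 37.0). SYT3, a synaptotagmin, and CHRDL1, a BMP antagonist, were 47.2-fold and 43.3-fold higher, with 0 reads in the alive library. Their bounds of the exact interval were 38.1 and 34.9. TNFSF11, the osteoclast differentiation factor RANKL, was 26.2-fold higher, also with 0 reads in the alive library, and its bound was 20.9. SERPINB13, a squamous serpin, was 26.7-fold higher (11.2 to 83.1).

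On the low side, FLT3, a receptor of haematopoietic progenitors and dendritic cells, was 99.1-fold lower in the spontaneous abortion than in the alive library (42.0 to 307). It was 6.44-fold lower in the stillborn library (4.66 to 9.09). GZMB was 37.2-fold lower (17.7 to 93.9) and GNLY 33.6-fold lower (15.1 to 93.1), as both were, less far, in the stillborn library. MHC-DPB1 (listed as LOC103221682), a class II histocompatibility gene, was at RPKM 0.888 against 30.1. IGFBP1, a binding protein of insulin-like growth factors made by decidua and fetal liver, was 29.6-fold lower (23.7 to 37.4), while FOXO1, a transcription factor on the same decidual list, was at RPKM 2.20 against 1.09. The Fc receptor FCGR2B was 20.6-fold lower, with 0 reads in the spontaneous abortion library and a bound of the exact interval of 16.1. PIK3CG, a phosphoinositide kinase of leukocytes, was 99.3-fold lower (17.2 to 3980), with 1 read. The macrophage genes CD68 and LYZ, at RPKM 5.46 and 4.18 against 4.37 and 4.42, were close to the alive library, while C1QB was 5.28-fold lower (1.39 to 29.5) and TYROBP, a signalling adaptor, 4.53-fold lower (1.87 to 12.5), each with fewer than 30 reads. Apart as lower were 2 of 14 lymphocyte, 1 of 13 monocyte and macrophage, 0 of 14 neutrophil and 1 of 10 decidual genes, and 0 of each as higher.

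Among the lists, oral and oesophageal squamous genes had a median log2 ratio of 0.88 at a percentile of 100, with 7 of 9 members above 0. CRNN was 8.43-fold higher (7.06 to 10.1) and EMP1, an epithelial membrane protein, was at RPKM 175 against 61.9. Epidermal genes had a median of 0.50 (99.89th percentile), fibroblast and matrix genes 0.51 (99.87th) and inflammatory genes 0.56 (99.71st), the last with 4 of 6 members above 0, and 3 of 6 on the scale of total assigned reads. ICAM1 was 7.01-fold higher (4.92 to 10.3) and the alarmin IL1A 6.33-fold higher (3.83 to 11.2). With a mean RPKM under 1, IL1A did not enter the median, while IL1RN did, at RPKM 22.1 against 22.4. The collagen COL1A2 was at RPKM 32.4 against 17.6. Hypoxia genes had a median of 0.47 (99.98th percentile), with 11 of 12 members above 0. Among them were BNIP3, a mitophagy receptor, at 152 against 92.5 and the glucose transporter SLC2A1 at 77.6 against 52.1. For stillborn over alive the hypoxia median was 0.35, where random lists spread wider, from -0.39 to 0.45 against -0.31 to 0.24 here. Between the losses it was -0.06, so this shift does not set the abortion library apart. Immediate early genes had a median of 0.32 (99th percentile), with FOS at 85.5 against 54.2. With the mean in place of the median this list lay within random lists, also at 0.32. For stillborn over alive its median was 0.26, within wider random lists.

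Interferon-stimulated genes were on the low side, with a median of -0.50 (0.01st percentile) and 12 of 13 members below 0. IFI6 was at RPKM 44.9 against 85.1 and OAS1, a sensor of double-stranded RNA, at 7.69 against 15.3. Ribosomal protein genes had a median of -0.28 (0.03rd percentile), with 67 of 72 below 0. Cell cycle genes had a median of -0.43 (0.14th percentile) with all 15 members below 0, but over members with a mean RPKM of at least 5 the median was -0.20, within the random lists.

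**Figure D2:**
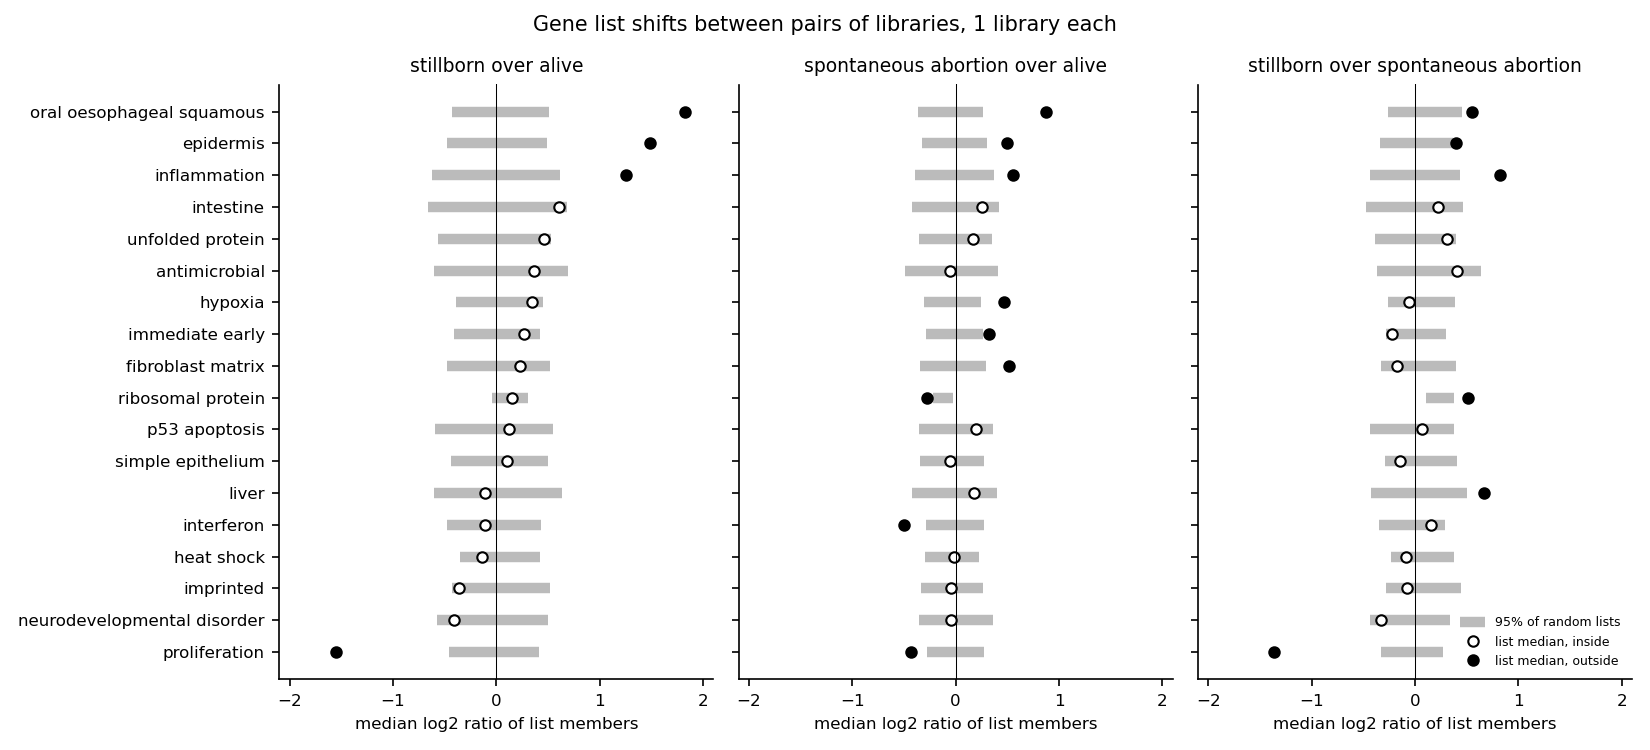
Median log2 ratio of each gene list with at least 5 members (points) for each pair of libraries, against the central 95% of random lists matched on mean expression (grey bars); filled points lie outside the bars. The squamous list stands at 1.83 and 0.88 and the proliferation list at -1.55 and -0.43 against the alive library.

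Setting the 2 losses against each other asks what parts a stillbirth from an abortion, and it found 388 genes apart as higher and 229 as lower in the stillborn library. TREM1, an activating receptor of neutrophils and monocytes, was 81.9-fold higher in the stillborn library. The macrophage chemokine CCL18 was 50.7-fold higher there and the T cell chemokine CCL5 34.8-fold. Each had 0 reads in the spontaneous abortion library, and the bounds of the exact interval were 65.7, 40.3 and 27.4. MUC7 was 83.8-fold higher (47.6 to 163) and SPRR3 30.8-fold higher (27.3 to 34.9). WDFY4, a gene of antigen cross-presentation in dendritic cells, was 90.4-fold higher (30.3 to 443). C4BPA, a complement inhibitor, was 33.6-fold higher, also with 0 reads in the spontaneous abortion library, and its bound was 26.4. Of 13 measured monocyte and macrophage markers, 6 were apart as higher and 0 as lower, as were 2 and 0 of 14 neutrophil genes. Among the former were C1QB at RPKM 4.35 against 0.194 and TYROBP at 4.39 against 0.280.

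On the low side in the stillborn library, the bone morphogenetic protein BMP5 was 39.0-fold lower (16.5 to 121), UNC5C 36.7-fold lower (12.4 to 180) and BDKRB1 25.3-fold lower (8.47 to 124). RFK, the riboflavin kinase, was 8.56-fold lower (7.56 to 9.73). RTL1 was 9.64-fold lower, with 0 stillborn reads and a bound of the exact interval of 7.57. Cell cycle genes had a median log2 ratio of -1.37 at a percentile of 0, all 15 members below 0, with MCM5 5.09-fold lower (3.51 to 7.63). Ribosomal protein genes had a median of 0.52 at a percentile of 100, with 72 of 72 members above 0 and 66 of 72 on the scale of total assigned reads. Inflammatory genes had a median of 0.82 (99.96th percentile) and squamous genes one of 0.56 (99.46th). The shifts of the liver list (0.66, 99.46th percentile) and of the epidermal list (0.39, 98.14th) lay within random lists when the mean replaced the median, at 0.31 and 0.40. With every library thinned to the smallest total, 407 genes were higher and 131 lower.

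**Figure D3:**
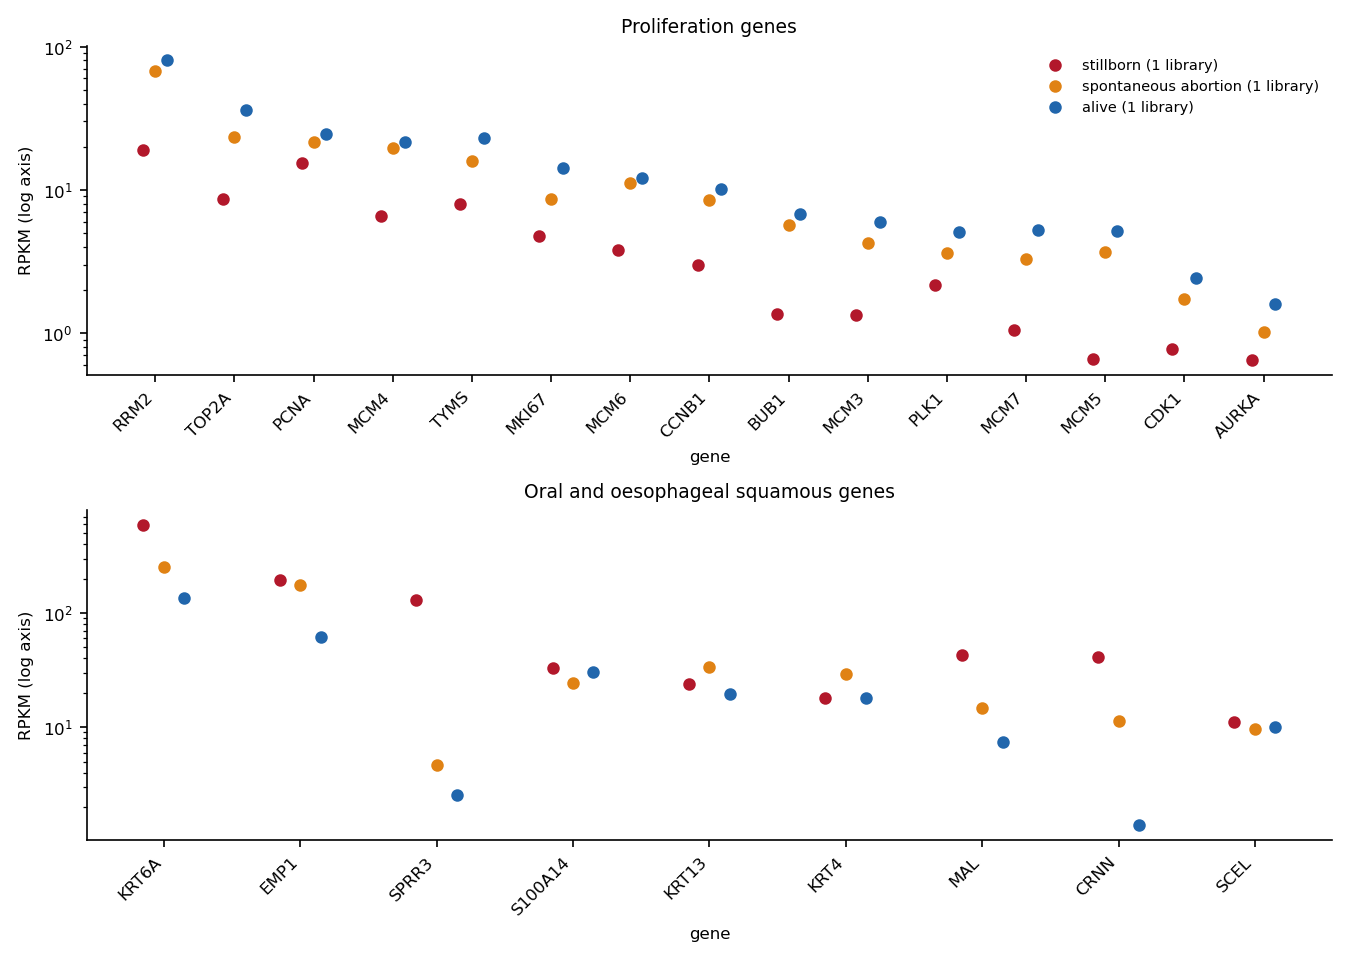
RPKM on a log axis of each proliferation gene (top) and each oral and oesophageal squamous gene (bottom) with a mean RPKM of at least 1; every point is 1 library. RRM2 stands at 19.1 in the stillborn, 67.8 in the spontaneous abortion and 79.9 in the alive library, and KRT6A at 588, 254 and 135.

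Set against both others at once, the stillborn library had 278 genes apart as higher and 110 as lower, the alive library 108 and 144, and the spontaneous abortion library 49 and 42. Across the 10229 genes with a mean RPKM of at least 1, which are not independent replicates, Spearman's rho was 0.881 for stillborn and alive, 0.945 for spontaneous abortion and alive, and 0.932 for the losses.

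A model of both losses against the alive library called 16 genes with limma and Benjamini-Hochberg adjustment, all higher in the losses, and 930 genes had an unadjusted p under 0.05. With log2(RPKM + 1) 12 genes were called as higher and 4 as lower in the losses, and with limma-voom 12 and 2. DDX3Y led those with a symbol, with a log2 difference of 5.66 (SE 0.459, adjusted p = 0.00107 from limma). OLFML3, an olfactomedin-like matrix protein, followed with 3.47 (SE 0.348, adjusted p = 0.00543 from limma), at RPKM 85.3 and 79.0 in the stillborn and abortion libraries against 7.86. PLAC9, placenta associated 9, differed by 3.18 (SE 0.340, adjusted p = 0.00811 from limma), at 65.6 and 70.3 against 7.96. GNAO1, a G protein alpha subunit of neurons, was at 13.1 and 10.5 against 1.40, and NCCRP1, an F-box-like protein of squamous epithelium, at 27.3 and 21.2 against 3.60, with adjusted p = 0.0199 and 0.0321 from limma. The other 11 called genes carry LOC numbers that matched no entry of the reference table. LOC103246967 was at RPKM 844 and 594 against 0.434, and LOC103223220 at 57.6 and 48.2 against 0. On simulated reads this model made false calls above the nominal level, so the calls here may include false ones.

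The call rests on 1 alive library, and its number depends on the setting. It fell with median-of-ratios factors and with the filter of at least 30 reads in 1 library. It also fell without the genes near 0 in the alive library. Those include most of the called genes, so this fall was largely by construction. Without a filter on low values the calls were lost. Adjusted p with median-of-ratios factors was 0.0209 for DDX3Y, 0.0499 for OLFML3, 0.0592 for PLAC9, 0.125 for GNAO1 and 0.180 for NCCRP1. With the stillborn library set alone against the other 2, the same model called 10 genes, with 1325 at an unadjusted p under 0.05 and 137 called by limma-voom. With the spontaneous abortion library alone it called 0 genes, with 56 at an unadjusted p under 0.05 and 0 by limma-voom.

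**Figure D4:**
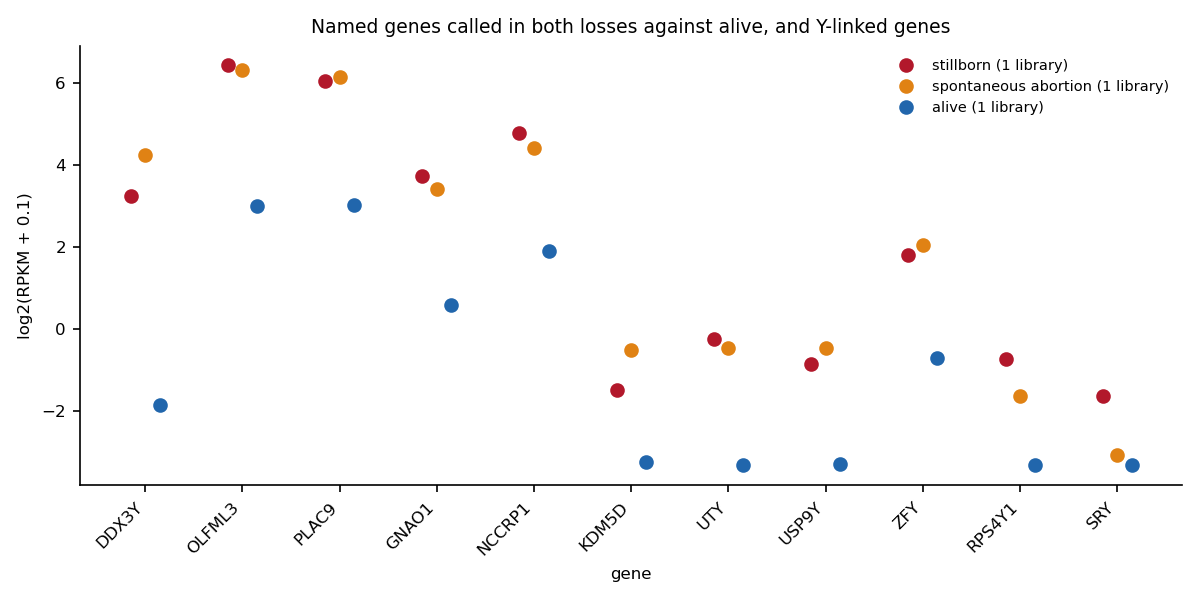
Log2(RPKM + 0.1) in each library (1 point each) of the 5 named genes called in both losses against alive and of the measured Y-linked genes. OLFML3 and PLAC9 stand at RPKM 85.3 and 65.6 in the stillborn library against 7.86 and 7.96 in the alive one.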

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

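For this part, the test of sex was chosen after its result was seen. Y-linked transcripts were read in the spontaneous abortion library, whose sex label is NA, above the alive library, whose label is F. The 7 measured Y-linked genes summed to RPKM 24.9 in the spontaneous abortion, 14.9 in the stillborn (label M) and 0.699 in the alive library. DDX3Y was at 18.8, 9.38 and 0.178, ZFY at 4.04, 3.36 and 0.512, USP9Y at 0.628, 0.457 and 0.00185, UTY at 0.626, 0.747 and 0.000848, and KDM5D at 0.595, 0.257 and 0.00626 in that order. RPS4Y1 had 3, 4 and 0 reads and SRY 1, 7 and 0.

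A pattern in the reads goes with this one. Of the 10229 genes tested, 12 lay under RPKM 1 in the alive library and at least 16-fold higher in both losses. A library at 0 was given 3 reads, and the same rule gave 5 genes for the stillborn and 4 for the spontaneous abortion library. The rule is separate from the fit of both losses, which did not call all of the 12, CHST15 among those left out. Reads of X-linked copies assigned to Y-linked genes would give alike ratios of DDX3Y to DDX3X in every library. That ratio was 1.01, 1.21 and 0.00851 in the stillborn, spontaneous abortion and alive libraries, a smallest step of 119 from alive to a loss, which argues against such reads for DDX3Y. The other Y-linked genes were not tested in this way, and ZFY held most of the Y-linked RPKM of the alive library. The summed Y-linked RPKM was 21.3 times the alive value in the lower of the losses, as a male fetus in both losses and a female one in the live pregnancy would give. Sex and outcome run together in these 3 samples, and each library comes from 1 pregnancy. For the genes of this pattern other than Y-linked ones, a difference of sex, of outcome or between single pregnancies stays open alike. Of those 12 genes, 1 is on the Y-linked list, DDX3Y, and 9 are LOC numbers without an entry in a reference table that holds no Y chromosome.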

How the results depend on the processing

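The model with total assigned reads, log2(RPKM + 1), the removal of genes near 0 in the alive library, the change of the lone library and the matching on length were chosen after seeing the data. The planned negative binomial count tests, the one reported and its alternative, were not run because the deposited values are RPKM. No paired analysis was possible because each status has 1 sample. Fewer reads allowed, or a lower fold, changed how many genes were apart by construction: 474 with at least 100 reads, 1865 with at least 10 and 3425 at 2-fold for stillborn against alive (1063 as reported), 169, 1134 and 1839 for spontaneous abortion against alive (523), and 212, 1177 and 2071 for stillborn against spontaneous abortion (617). Thinning, protein-coding genes alone and other scalings kept those totals within 1.5 times. The model of both losses called 16 genes as reported, 9 with median-of-ratios factors, 6 with at least 30 reads in 1 library, 2 without 27 genes near 0 in the alive library (under RPKM 1, and at least 16 times that RPKM in both losses, with values of 0 left as they are), and 0 of 23276 without a filter, where 1554 had an unadjusted p under 0.05. With the stillborn library alone it called 10 and with the spontaneous abortion library alone 0. The genes near 0 that were removed include most of the called genes, so that fall was largely by construction. For the other settings the cause was not tested. For the 7 named genes of that model, 35 alternatives kept the call and 18 lost it, all in the same direction; each gene lost it without a filter. With voom on the recovered reads, 137 genes were called for the stillborn library alone. Genes detected in the other 2 libraries numbered 13755 to 14314 when 1 library was left out. For list shifts outside the central 95% of random lists, 124 alternatives kept their side and 5 did not. Over members with a mean RPKM of at least 5 these were cell cycle genes in spontaneous abortion against alive, at -0.20, and epidermal genes in stillborn against spontaneous abortion, at 0.23. With the mean they were the liver (0.31) and epidermal (0.40) lists of that last pair and immediate early genes in spontaneous abortion against alive (0.32). The imprinted list moved outside with the mean, at -0.55 for stillborn against alive and -0.29 for stillborn against spontaneous abortion; the cause was not tested. Ratios of named genes kept their call in 317 alternatives and lost it in 3, with none in the opposite direction. Depth limits the low genes most, with 3 reads as the floor for a library at 0.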

Other observations

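The tests of scaling, of dilution and of depth on the leukocyte genes counted as apart were chosen after the result they bear on was seen. Several genes not described above, chosen after their values were seen, had their highest RPKM in the stillborn library. GPNMB, a glycoprotein of macrophages, was at RPKM 21.3 in the stillborn library against 0.912 in the spontaneous abortion one, with 1023 reads against 74 there and 55 in the alive library. The secreted phosphoprotein SPP1 was at 71.1 against 6.20 and 5.76, chitotriosidase (CHIT1), made by activated macrophages, at 20.9 against 0.699 and 0.325, the leukocyte lysosomal protein LAPTM5 at 23.7 against 1.04 and 1.83, and RAC2, a GTPase of blood cells, at 26.7 against 1.23 and 1.66.

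Cell cycle genes were low in the stillborn library, at a median log2 ratio of -1.55 to the alive one. A scaling factor moves every gene alike, and the list's median less that of all tested genes was -1.54 (SD of the members 0.52), which argues against scaling by a few abundant genes. The median of all tested genes was already -0.013 after TMM, so this value restates the shift and is no separate support for it. Taking out a running median over recovered gene length left it at -1.53, with a length for all 15 members, which argues against a length trend. Dilution by RNA of other cells would lower the simple epithelial and fibroblast lists about as far, and their medians were 0.10 (SD 0.78) and 0.23 (SD 0.52), or -0.05 and 0.07 on total assigned reads, which argues against dilution of all these cells alike. Of the 10 simple epithelial members, 5 lay above 0 and 5 below. KRT19, the most abundant, was at -0.65 and KRT8, behind KRT18 and KRT7 in abundance, at -1.22. Dilution of part of the epithelium therefore stays open, as do a lower share of dividing cells and a difference in gestational age, which were not tested.

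Leukocyte genes low in the spontaneous abortion library were examined with 24 pan-leukocyte genes chosen before their values were seen. Of the 22 with reads, 59.1% had their lowest RPKM in the spontaneous abortion library, where a share over 60% would have gone with a lower RNA share of leukocytes and one under 40% against it. With every library thinned to the smallest total the share was 54.5%, with 2 more genes tied for the lowest value. It lies between the same bounds, so the share alone does not decide on depth for this list. The list's median RPKM in the spontaneous abortion library was 0.296 at full depth and 0.311 when thinned. All 8 leukocyte genes apart as lower than in the alive library (100%) stayed so when thinned, where 346 of all 523 genes apart did. This could hardly come out otherwise, because thinning took reads mainly from the spontaneous abortion library, where these genes were already low. Among all genes, those apart as lower numbered 207 before and 176 after thinning, and those higher 316 and 196. Some of the 8, such as FLT3, were taken from the genes named above as low. The spontaneous abortion library was the deepest, which argues against a shortage of reads there for those genes and for the pan-leukocyte list. The list's median RPKM was 0.296 in the spontaneous abortion and 0.303 in the alive library, and 18 of the 22 genes had their highest value in the stillborn library, so the difference may lie as much in that library. Of 12 genes of uterine natural killer cells, 7 had reads; 1 was lowest in the spontaneous abortion library alone and 3 shared their lowest value, 0, between it and another library, with GZMA at 0.375, 0.630 and 3.46 in the stillborn, spontaneous abortion and alive libraries.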
